A study of Drosophila melanogaster with 3 samples.

How the data were processed

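ChIP-seq peaks of 3 biological replicates of embryos with GFP-tagged fd64A (FoxL1) were analysed. Per the labels, chromatin was sheared by sonication to 200 to 800 bp, the embryos were of both sexes, and each biological replicate has 1 technical replicate. The labels disagree in places. A free-text description calls each sample an input control, while the assay title, the antibody label and a separate control experiment mark it as an immunoprecipitation, and it was treated as such. The age label does not read as an age in hours, so the 8 to 14 hours of the source name were used. All replicates come from 1 donor strain, and the p-values that use single peaks or genes measure the spread between these items, not between fly lines.

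Peak lists on dm6 were used as deposited, in narrowPeak format per the file headers. Per the deposited file descriptions, a relaxed list of peaks and background was called for each replicate and for the pooled replicates against the same input alignment, as input to the IDR procedure. The IDR list was derived from these. The aligner, the peak caller, their settings and the IDR threshold are not given in the sources used here. The peak strength is the deposited signal of column 7, the authors' own value, which was used only to rank and describe peaks within a list. The deposited −log10 q-value of column 9 was used only to count peaks with q under 0.05. All 2919 IDR peaks were in the pooled list and were its 2919 strongest by signal, of which 2784 had q under 0.05. Most peaks have a fixed width (404 bp for 71.2% of IDR peaks), so widths were not compared, and 124 IDR peaks overlap another. The shared input and the fixed number of 30000 relaxed peaks mean that numbers of relaxed peaks carry no information on enrichment, and that an error in the input would be shared by all replicates.

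The reference was the NCBI assembly of release 6, whose arm lengths contain every peak, with gene models of Ensembl release 115 without transposable elements. Only the 6 arms 2L, 2R, 3L, 3R, 4 and X were used. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, with random seed 1. For comparisons between replicates the leading 2919 peaks of each by signal were taken, as many as the IDR list holds, and values are given as mean ± SD over 3 replicates. With 3 replicates a two-sided sign test cannot go below 0.25, so the replicates serve as a measure of spread and the tests are over peaks or genes.

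Overlaps needed at least 1 bp and were compared with 100 circular shifts along the arms. Summits were assigned to promoter (within 500 bp of a TSS), 5′ untranslated region, 3′ untranslated region, coding exon, non-coding exon, intron or intergenic sequence, in that order, and compared with 1000 random placements on the same arms. Arm shares were compared with the arms' sequenced bases by a two-sided exact binomial test. Motifs were searched on both strands within 50 bp of the summit and in the same windows 500 bp to each side, and compared by a two-sided Fisher's exact test. Flanks can themselves hold binding sites, which would lower the ratios. A difference in base composition between summits and flanks was not corrected for and could raise or lower them. Fisher's test treats the windows as independent and does not use the pairing of each summit with its own flanks. The same test was run for all 7-base words, with reverse complements merged. A gene was counted as carrying a peak where a summit lay from 2000 bp upstream to its end. Each list was set against 10000 random lists matched on gene length in 20 bins, in a two-sided permutation test. Trends over the IDR list cut by signal into 4 groups used 100000 permutations. The Benjamini-Hochberg adjustment was made within each family at a threshold of 0.05. Wilson intervals of 95% cover counting error only.

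The 15 gene lists and 26 motifs were fixed before the data were examined, as were the tests and the alternatives of the closing section other than those named there as chosen later. Of the listed names, 4 matched no single gene of the annotation and were left out. The genes named are those nearest to the 20 strongest peaks, the 10 with the most summits, up to 4 members of each list with the strongest peak and up to 2 members without one that come first in the alphabet, FoxL1, w for comparison, and genes that share a named peak or span. In families added later they are all members with a peak where these are 3 or fewer, and otherwise the 4 that come first in the alphabet, for the families nearest to the threshold.

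The forkhead share, the searches over words and motifs, the overlap of replicates, the promoter share, the gene lists and the trend with peak strength were tested on simulated data, and the other statistics were not. For the forkhead share, words planted at random positions of the genome gave 25.7% where 25.6% had been set, over 2919 windows. With nothing planted the ratio to flanks was 0.988. Random positions do not hold a difference in base composition between summits and flanks, so this was not tested. The planted word ranked 1 among 8192 words. For the gene lists, 2.5% of 200 lists passed before adjustment when length alone set binding. Of 200 lists of 25 genes, 92.5% passed before adjustment when binding was 2 times as frequent. Simulated binding was more frequent than in the data, and many of the fixed lists hold fewer genes. The second value is therefore not the power of the adjusted test for those lists. Without any trend, 5.5% of 200 draws passed the trend test, and 3% of 200 random words passed Fisher's test before adjustment. A planted overlap of 60% was recovered as 60.5%, and a planted promoter share of 39.4% as 39.4%.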

Results

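Chromatin immunoprecipitation sequencing (ChIP-seq) was carried out on embryos of Drosophila melanogaster aged 8 to 14 hours, males and females together, from a line that carries fd64A fused to green fluorescent protein (GFP) at its C terminus. fd64A, listed in the annotation as FoxL1 (FBgn0004895), encodes a transcription factor with a forkhead DNA-binding domain. The labels give 1 group of 3 biological replicates from 1 fly strain and no second condition, so the comparisons are between replicates, between peaks and the surrounding genome, and between groups of genes. Each replicate was represented by a relaxed list of 30000 peaks, and a further list of 30000 peaks came from the pooled replicates. A final list of 2919 peaks was deposited as thresholded by the authors on the irreproducible discovery rate (IDR). It held the 2919 strongest pooled peaks by signal, which does not show that each peak by itself was reproducible. Positions are on dm6. Read numbers are not given in the sources used here, so the depth is unknown. Peaks with q under 0.05 numbered 4964 in replicate 1, 3017 in replicate 2 and 1598 in replicate 3.

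The peaks with the highest signal lay beside px, Ugalt, hll, CG11050 and sbb. The strongest, with a signal of 2739 as deposited, covered 2R:22514119–22514486, 210 bp upstream of the nearest transcription start site (TSS) of px (plexus, a gene of wing vein patterning). The second lay 44 bp upstream of the TSS of Ugalt, a UDP-galactose transporter, at X:2703701–2704070. The peak of rank 5 lay in an intron of sbb (scribbler, a nuclear regulator also known as brakeless) at 2R:18336862–18337383, and 2 forkhead words (RTAAAYA) lay within 50 bp of its summit. Other genes nearest to the 20 strongest peaks included cno (canoe, an adherens junction protein), cbt (cabut, a zinc-finger factor), ph-p (polyhomeotic proximal, a Polycomb group protein), tara, Chro (Chromator, a chromatin protein) and the kinase gene Lk6. Also nearest to such peaks were CG14100, CG1888, jp, CenG1A, CG13323, PNPase, CG18549, CG9663 and CG11309. All 20 were among the leading 2919 peaks of all 3 replicates. Of the 20 summits, 11 lay within 500 bp of an annotated TSS, 6 in introns and 3 between genes, and 9 had a forkhead word within 50 bp. The promoter summit nearest to hll belonged to the TSS of another transcript, since it lay 2909 bp upstream of the nearest TSS of hll itself.

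The genes with the most summits, a count that grows with gene length, were CG1677 and sbb. They each held 13 summits between 2000 bp upstream and the end of the gene, with 12.3 ± 0.577 and 11.7 ± 2.31 (mean ± SD, n = 3) among the leading peaks of the replicates. Next came bun (bunched, of the TSC22 family), shn (schnurri, a zinc-finger effector of Dpp signalling) and ush (u-shaped, a cofactor of GATA factors), with 11 each. CHES-1-like, a forkhead gene of 27.1 kb, held 9 summits, or 31.0 per 100 kb with the upstream part, the highest density of the 10 genes with the most summits. The others were SNF4Agamma with 9, and CG5953, the nuclear receptor gene Hr4 and the kinase gene Raf with 8 each. The gene hth also held 8, so the 10 genes were cut within a tie. The span of CG1677 (X:7281089–7405797) includes the peak at X:7306936–7307339 that was also counted for brk. SNF4Agamma varied most between replicates, with 8, 10 and 4 summits.

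The replicates shared most of their leading peaks. Among the 2919 strongest peaks of each, replicates 1 and 2 shared 68.2%, replicates 1 and 3 shared 72.6% and replicates 2 and 3 shared 67.6%, counting overlaps of at least 1 bp. The mean was 69.5% ± 2.75 (SD over 3 pairs), against 1.55% when one list was moved along the chromosome arms. Each pair exceeded all 100 such shifts (one-sided permutation p = 0.0099, the smallest that 100 shifts allow). Of the 2919 peaks in the IDR list, 83.8%, 78.4% and 80.6% overlapped a leading peak of replicates 1, 2 and 3, a mean of 80.9% ± 2.70 (SD, n = 3). A leading peak was found in all 3 replicates for 1688 of them (57.8%), in 2 for 816, in 1 for 391 and in none for 24. Across IDR peaks, the Spearman correlation of the replicates' signals averaged 0.657 ± 0.0578 (SD over 3 pairs). It was 0.614 for replicates 1 and 2, 0.723 for replicates 1 and 3 and 0.634 for replicates 2 and 3. These correlations are across peaks, which are not independent replicates.

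Promoters and introns held most summits. Within 500 bp of a TSS lay 1230 summits, 42.1% of the IDR list (95% Wilson interval 40.4 to 43.9) against 13.6% of positions placed at random on the same arms, a 3.09-fold difference. Positions placed within pooled relaxed peaks lay at promoters in 27.4% of cases, which lowers the difference to 1.54-fold. With exons assigned before promoters, the promoter share was 27.0% against 6.52% at random. With promoters assigned first, the leading peaks of the replicates gave 43.5% ± 2.12 (SD, n = 3). Introns held 1222 summits, 41.9% against 39.2% at random. Summits were scarce in coding exons, with 9 (0.308%) against 13.1% at random, in 3′ untranslated regions, with 27 (0.925% against 4.95%), and between genes, with 372 (12.7% against 27.5%). These 5 classes passed the threshold at a Benjamini-Hochberg adjusted p = 0.0028 over 7 classes, from a raw permutation p = 0.002, the smallest that 1000 placements allow. With exons assigned first all 7 classes passed, and 4 passed in the stronger 1459 peaks. The differences in promoters, coding exons, 3′ untranslated regions and intergenic sequence exceeded the spread between replicates. The intron value did not, since the replicates averaged 40.3% ± 1.59. The shares in 5′ untranslated regions (permutation test, adjusted p = 0.67) and non-coding exons (adjusted p = 0.061) did not pass. The median distance from a summit to the nearest TSS was 794 bp, and 483 summits (16.5%) lay over 5000 bp from any TSS.

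**Figure D1:**
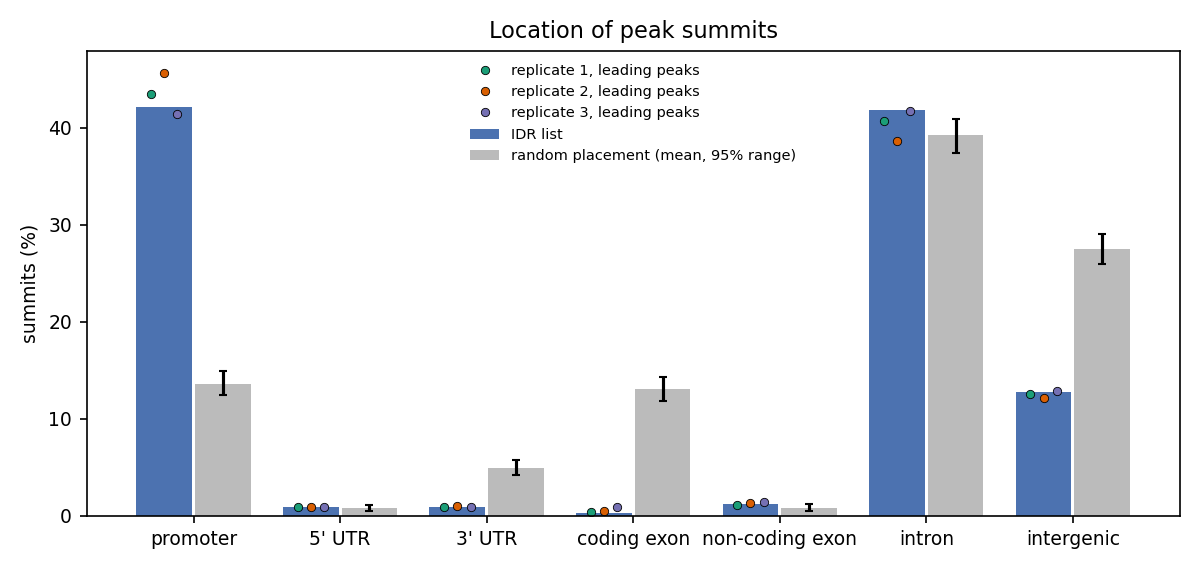
Share of summits (percent, vertical axis) in each class of sequence (horizontal axis) for the IDR list (blue bars), for random placement on the same arms (grey bars, mean with 95% range as error bars) and for the leading 2919 peaks of each of the 3 replicates (points). Promoters hold 42.1% of IDR summits against 13.6% at random, and coding exons 0.308% against 13.1%.

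By chromosome arm, the X held fewer summits than its length gives. It makes up 17.6% of the sequenced bases of the 6 arms and carried 437 summits, 0.852 times its share of length (two-sided exact binomial test, adjusted p = 0.000591 over 6 arms). The replicates gave 14.9% ± 0.494 (SD, n = 3). With embryos of both sexes the X is at lower copy than the autosomes, and the share by length does not take this into account. In the stronger 1459 peaks the X ratio was 0.956 and did not pass (exact binomial test, adjusted p = 0.54). Chromosome 4, which is small and rich in repeats, held 4 summits, 0.137% against 0.996% of bases (exact binomial test, adjusted p = 7.62e-08). The replicates gave 0.206% ± 0.214 (SD, n = 3) for this chromosome, from 0.0343% to 0.445%. Averaged over the leading peaks of 2 replicates, with 1 left out each time, its ratio was 0.0860 to 0.292, against 0.138 in the IDR list. Arm 2L held 19.2% against 17.6% (exact binomial test, adjusted p = 0.0446), which no longer passed without replicate 2 or without replicate 3 (with a ratio of 1.09 in each case, adjusted p = 0.069) or in the stronger 1459 peaks (ratio 1.09, adjusted p = 0.35), and 2R, 3L and 3R did not pass (adjusted p = 0.179, 0.109 and 0.474). Against the pooled relaxed list, of which the X held 13.9%, the X share of the IDR list was higher and not lower, at 1.07 times (exact binomial test, adjusted p = 0.24). Against the same list, chromosome 4 stood at 2.28 times (exact binomial test, adjusted p = 0.24).

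Forkhead sequence was concentrated under the summits. The word RTAAAYA, which forkhead proteins are known to bind, lay within 50 bp of 872 of 2919 summits (29.9%, 95% Wilson interval 28.2 to 31.6) and in 16.5% of windows 500 bp to each side. The ratio was 1.81 (95% interval 1.67 to 1.96, Fisher's exact test, adjusted p = 4.45e-44 over 26 motifs). The leading peaks of the 3 replicates gave 28.9% ± 1.64 (SD) at summits and 16.0% ± 0.708 in flanks, and the word was more frequent at summits in each. The stricter word GTAAACA lay at 8.12% of summits and 2.12% of flanks, a ratio of 3.82 (3.09 to 4.73). The related consensus AYAAAYA lay at 30.5% of summits and 18.4% of flanks, a ratio of 1.65.

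**Figure D2:**
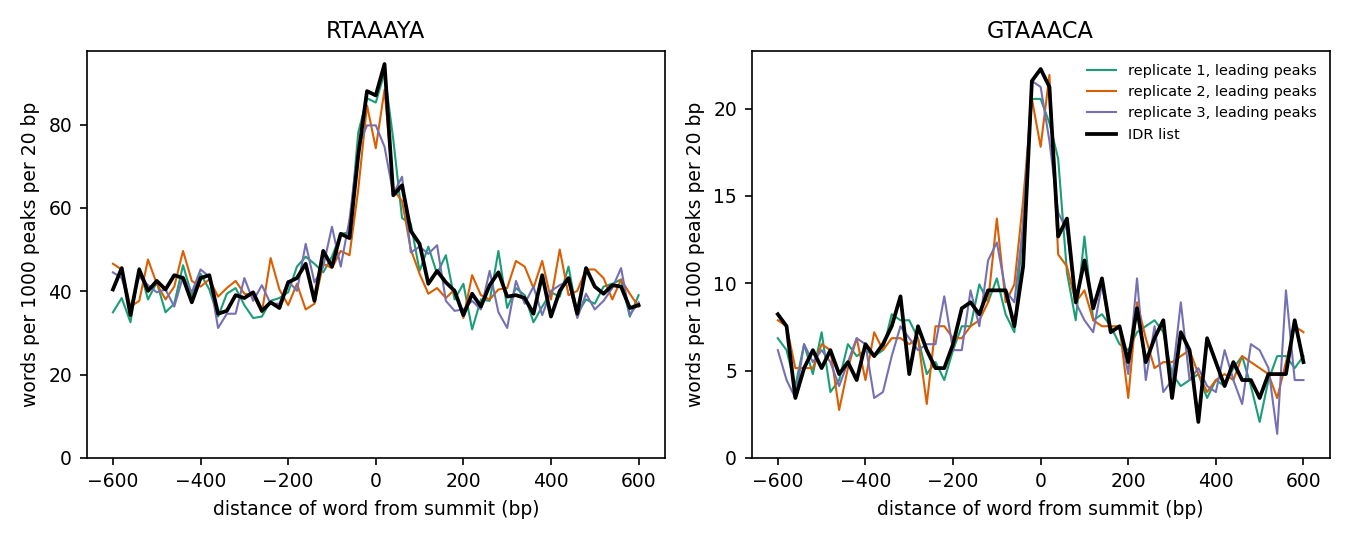
Number of forkhead words per 1000 peaks in bins of 20 bp (vertical axis) against the distance from the summit in bp (horizontal axis), for RTAAAYA (left) and GTAAACA (right), in the IDR list (black) and in the leading 2919 peaks of each replicate (colours). All 4 lines have their highest bin centred within 20 bp of the summit for both words.

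A search over all 8192 words of 7 bases, with no motif given, placed GTAAACA first, and GTAAATA first with flanks 1000 bp away. In the main search GTAAACA was followed by GTAAATA (2.81-fold over flanks, adjusted p = 7.11e-26), ACAAATA (2.46-fold, adjusted p = 1.29e-21), TAAACAA (2.21-fold) and GCAAACA (2.53-fold), by Fisher's exact test. In all, 168 words were more frequent at summits and 153 less frequent. All 6 words that match RTAAAYA or AYAAAYA were among the more frequent, as were 41 of the 96 words with AAACA or AAATA in them.

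Among the other 23 motifs of the fixed list, 4 were more frequent at summits and 2 less frequent, and 17 of the 26 did not pass. The GATA site WGATAA lay at 16.4% of summits against 13.4% of flanks, a ratio of 1.23 (Fisher's exact test, adjusted p = 0.000827). By the same exact test, rarer sites had larger ratios on few windows: 3.52 for paired CGATA words of the insulator protein BEAF-32 (37 summits, adjusted p = 1.38e-05), 3.06 for the DREF site (26 summits, adjusted p = 0.00121) and 3.43 for the ETS site (12 summits, adjusted p = 0.035). The DREF site lay at 24 of 1230 promoter summits (ratio 4) but at only 2 of the 1689 others (ratio 0.8). For BEAF-32 the ratio was 4.14 at promoter summits. At the others it was 2.29 and did not pass (Fisher's exact test, adjusted p = 0.171). The Scalloped site (ratio 0.716) and the Su(H) site (0.741) were less frequent, both at an adjusted p = 0.0157 in Fisher's test. Each of these 6 motifs had the same direction in all 3 replicates. The search over words gave 153 less frequent ones, the first by p being CTGCTCC (0.274-fold) and GAGGAGC (0.230-fold). Base composition was not corrected for, so the deficits of the Scalloped and Su(H) sites are not shown to be particular to these sites. The Mef2 site (ratio 1.11, adjusted p = 0.544) and the Tinman site (0.879, adjusted p = 0.466) did not pass Fisher's test. In Fisher's test over all summits, the GAGA factor site (1.18, adjusted p = 0.392) and the Zelda site (1.09, adjusted p = 0.837) did not pass either. At the 1230 promoter summits alone, the GAGA factor site passed (3.74% against 2.36% of flanks, ratio 1.59, Fisher's exact test, adjusted p = 0.0427). At the 1689 other summits its ratio was 0.949 and did not pass (Fisher's exact test, adjusted p = 0.872). At the 346 promoter summits among the strongest 730 peaks, its ratio was 1.29 and did not pass Fisher's exact test. With the stronger 1459 peaks alone, the GATA, BEAF-32, ETS, Scalloped and Su(H) sites no longer passed (Fisher's test, adjusted p = 0.055, 0.074, 0.06, 0.1 and 0.49). The ratios there were 1.22 for GATA and 0.715 for Scalloped, close to those of the whole list, 4.5 for ETS, 2.27 for BEAF-32 and 0.851 for Su(H). The ETS site also did not pass against flanks 1000 bp away (ratio 2.4, Fisher's test, adjusted p = 0.084).

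Stronger peaks carried forkhead words more often. With the IDR list cut by signal into 3 groups of 730 and a last of 729, the share was 36.4% in the strongest, 30.7% in the next, 27.3% in the next and 25.1% in the weakest, with ratios to flanks of 2.09, 1.82, 1.74 and 1.54. The trend passed a two-sided permutation test (p = 1e-05, the smallest that 100000 permutations give). The promoter share was 47.4%, 38.9%, 40.1% and 42.1% over the same groups and showed no trend past the threshold (permutation p = 0.075).

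Of 13945 protein-coding genes, 2362 (16.9%) carried a summit between 2000 bp upstream and the gene's end. Cytosolic ribosomal protein genes did so most often of the 15 fixed lists, with 65 of 92 (70.7%, 95% Wilson interval 60.7 to 79.0) against 8.90 in lists matched on gene length, a 7.30-fold difference. It was 4.16-fold without length matching and 3.53-fold with matching among genes with a pooled relaxed summit near a TSS, the latter chosen after seeing the data. The replicates gave 66.3% ± 2.88 (SD, n = 3). RpS27 had the strongest of these peaks, at 3R:25247348–25247665 with IDR rank 70. RpL7 (rank 81), RpL14 (rank 134) and RpS4 (rank 135) followed, all with promoter summits, while RpL10 and RpL10Aa carried none. Chemosensory receptor genes were at the other end, with 2 of 179 against 21.6 in matched lists, a ratio of 0.0928. The 2 were Or88a and Gr32a, and Gr10a and Gr10b were among those without a peak. Matched among genes with a pooled relaxed summit near a TSS, a setting chosen after seeing the data, 19 of the receptor genes were left, none of them carried a peak (ratio 0), and the list no longer passed (permutation adjusted p = 0.075). In the main test both lists passed at an adjusted p = 0.0015 over 15 lists, from a raw permutation p = 0.0002, the smallest that 10000 lists give.

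Genes of the salivary gland, a tissue formed during the sampled hours, carried peaks in 9 of 14 cases against 4.07 in matched lists (2.21-fold, permutation test, adjusted p = 0.043). The strongest lay at the promoter of fkh, which encodes the forkhead factor needed for gland formation, at 3R:28585229–28585625 (rank 47). Others lay at crb (crumbs, an apical membrane protein, rank 381), rib (ribbon, rank 506) and ps (pasilla, rank 602), while hkb and PH4alphaSG1 had none. The replicates gave 52.4% ± 4.12 (SD, n = 3) of the list. Counting genes found in both other replicates when 1 was left out, the list no longer passed in any case (ratios 2.15, 1.83 and 1.83, permutation test, adjusted p = 0.16, 0.38 and 0.38). Signalling genes carried peaks in 16 of 27 cases against 9.54 (1.68-fold, permutation test, adjusted p = 0.043), with 60.5% ± 5.66 (SD, n = 3) in the replicates. They included aos (argos, a secreted antagonist of EGF receptor signalling, rank 86), the EGF receptor ligand gene vn (vein, rank 125), the Wnt receptor gene fz (rank 151) and the Hedgehog receptor gene ptc (rank 337), while arm and E(spl)m8-HLH had none. With summits counted only within 1000 bp of a TSS, neither the salivary gland list (1.91-fold, permutation test, adjusted p = 0.6) nor the signalling list (1.22-fold, adjusted p = 0.99) passed. The same held with matching among genes with a pooled relaxed summit near a TSS (1.93-fold and 1.39-fold, permutation test, adjusted p = 0.16 and 0.24), and for the salivary gland list in the stronger 1459 peaks (2.00-fold, adjusted p = 0.42).

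The remaining 11 lists did not pass the threshold in the permutation test. Of 17 forkhead family genes, 6 carried a peak against 3.59 in matched lists (permutation adjusted p = 0.46). They included fkh, CHES-1-like, FoxK (rank 216) and jumu (rank 614), and croc and fd102C had none. Of fkh, CHES-1-like, FoxK and jumu, only jumu had a forkhead word within 50 bp of its strongest summit. Somatic muscle regulators had 9 of 29 against 9.99 (permutation adjusted p = 0.99). Among these were Mef2, the myogenic factor, with 5 summits and a promoter peak of rank 27 at 2R:9959753–9960086, kirre (7 summits, rank 168), zfh1 and mbc, while ap and ara had none. No forkhead word lay within 50 bp of the strongest summits of Mef2, kirre, zfh1 and mbc. Sarcomere genes had 5 of 21 against 6.52 (permutation adjusted p = 0.86), with TpnC73F (rank 457) and Msp300 (rank 740) ahead of sls and Zasp52, and none at Act57B or Act87E. Genes of visceral and cardiac mesoderm had 9 of 21 against 6.34 (permutation adjusted p = 0.46), with org-1 (rank 236), tin (tinman, rank 511) and Fas3 (rank 699) and none at Alk or bap. The peak assigned to Sur in that list is the same as that of RpL7.

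Guidance genes had 14 of 30 against 12.8 (permutation adjusted p = 0.96), among them the Netrin receptor gene fra (frazzled, rank 73) and its ligand gene NetB (rank 221), each with a forkhead word under the summit. Neuronal and glial genes had 5 of 25 against 8.25 (permutation adjusted p = 0.46), led by elav (rank 113) and moody (rank 444), with none at ase or brp. Epidermal genes had 5 of 17 against 4.96 (permutation adjusted p = 1), including sn (singed), grh (grainy head) and vri. Tracheal genes had 3 of 11 against 3.43 (permutation adjusted p = 1), namely pio, bnl and trh, with none at btl or dyl. Gut genes had 7 of 15 against 4.58 (permutation adjusted p = 0.46), led by otp (rank 136), cad (rank 674), lab and bowl, with none at byn or drm. Hox genes and cofactors had 3 of 10 against 4.35 (permutation adjusted p = 0.86), namely lab, hth (8 summits) and Antp, with none at abd-A or Abd-B. Fat body and hemocyte genes had 1 of 16 against 4.74 (raw permutation p = 0.042, adjusted p = 0.13). The 1 gene was ush, whose strongest peak is also the one nearest to cbt.

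**Figure D3:**
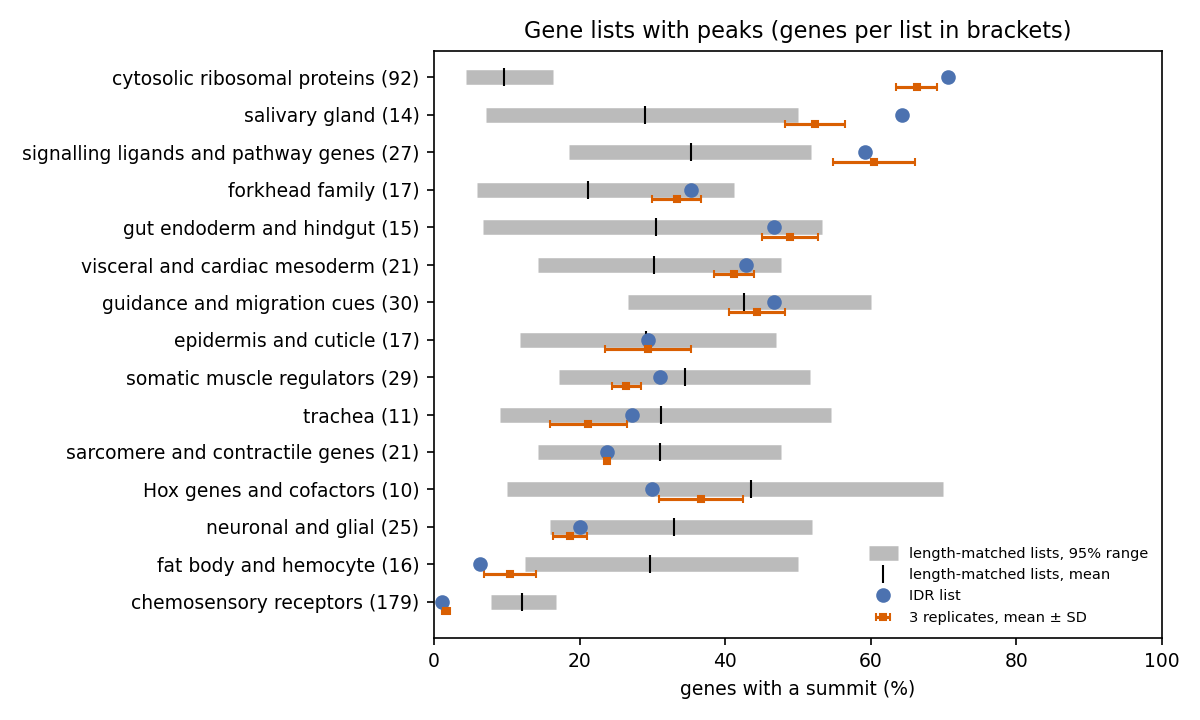
Share of the genes of each fixed list that carried a summit (percent, horizontal axis), with lists on the vertical axis and their sizes in brackets. Circles give the IDR list, squares the mean ± SD of the 3 replicates, ticks and grey bars the mean and 95% range of lists matched on gene length. Ribosomal protein genes stand at 70.7% against a matched mean of 9.67%, and chemosensory receptor genes at 1.12%, below the range of matched lists.

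The tagged gene itself carried 1 IDR summit by the rule used for genes, and a second lay further upstream. FoxL1 lies on the plus strand at 3L:4018878–4021279, and within 20000 bp of it lay 2 IDR summits. One was at 4016954, or −1924 bp from its TSS (peak 4016902–4017061, rank 852), and the other at 4014321, or −4557 bp (peak 4014119–4014522, rank 1746). Both lay between genes, were leading peaks in all 3 replicates and had 1 forkhead word within 50 bp. These words lay near the edge of the window, at −42 and −41 bp from the summits. Over all protein-coding genes, 64.4% had fewer IDR summits within the same distance and 80.8% had at most as many. In the pooled relaxed list, 28 summits lay within 20000 bp, against a median of 12, and 95.5% of genes had fewer. In the relaxed lists of replicates 1, 2 and 3, 26, 25 and 30 summits lay there, and 94.4%, 91.7% and 97.9% of genes had fewer. Among the 697 genes of like length, 97.6% had fewer pooled relaxed summits. Around the eye colour gene w (white), a common transgene marker, 0 IDR and 8 pooled relaxed summits lay within 20000 bp, and 24.6% of genes had fewer of the latter.

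**Figure D4:**
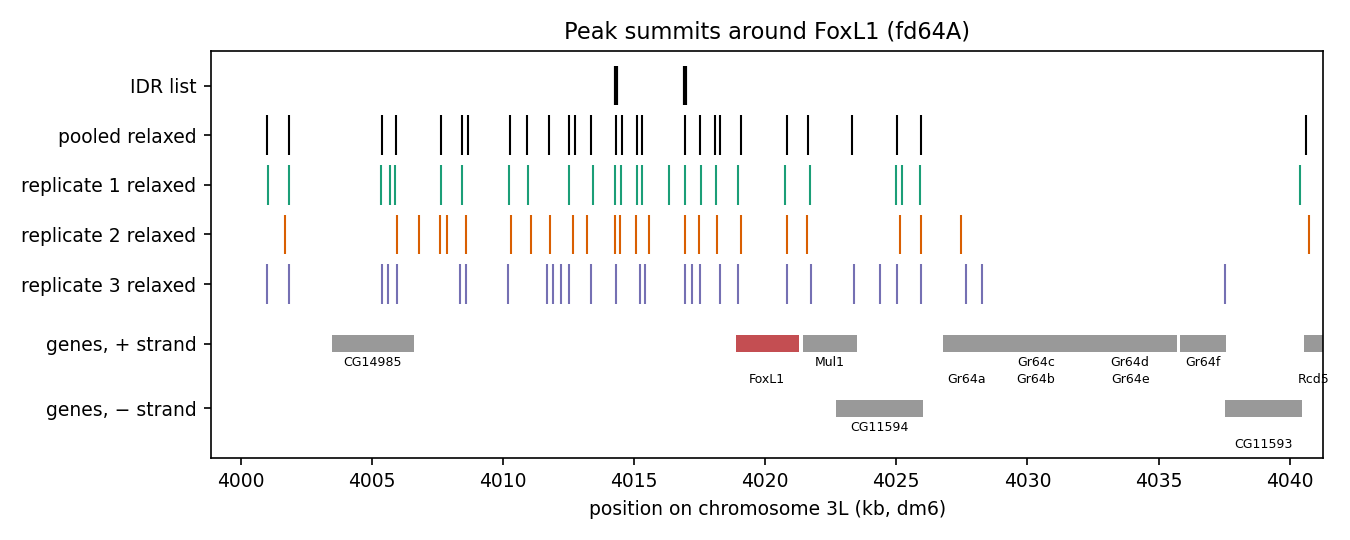
Map of 3L from 20000 bp before to 20000 bp after FoxL1 (horizontal axis, position in kb on dm6), with each peak summit of the IDR list, the pooled relaxed list and the 3 relaxed replicate lists as a vertical line in its own row, and protein-coding genes as boxes below (FoxL1 in red). The 2 IDR summits lie upstream of FoxL1, and 28 pooled relaxed summits lie in the window.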

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

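The tests of binding by the tagged protein at its own locus and of forkhead words at ribosomal against other promoters were chosen only after the results were seen. Apart from binding of the protein at its own locus and forkhead sites beyond the authors' threshold, no biological explanation was tested, since the design has 1 group.

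Forkhead sequence was also present in peaks that the final list leaves out. At the pooled summits ranked 2920 to 5838, RTAAAYA lay within 50 bp of 21.9%, against 15.9% of flanks, above the level of the flanking control windows (Fisher's exact test, p = 1.5e-11). GTAAACA was 2.82 times as frequent there as in flanks.

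Ribosomal protein genes carried peaks far more often than other genes of like length, yet few of these peaks had forkhead words. A peak that lies at a neighbouring gene away from the TSS is argued against by the position. Of the 92 genes, 63 had a summit within 200 bp of their own TSS, against 4.41 in lists matched on gene length (permutation p = 0.0002, the smallest that 10000 lists give). Whether the TSS of a neighbour lay equally near was not tested, so the test cannot decide on peaks of shared promoters. Enrichment of highly transcribed genes without specific binding is a candidate explanation: RTAAAYA lay at 4 of the 65 strongest summits, 0.381 times the share in flanks (95% interval 0.136 to 1.06), and at 6.25% of the 64 that are promoter summits against 26.5% of the other 1166 promoter summits (Fisher's exact test, p = 9e-05). Recruitment by another protein would give the same values and was not tested. If polymerase III genes were enriched as well, more tRNA genes would have peaks than by chance, but 13 of 290 had a summit within 500 bp, against a mean of 5.98 and a 95% range of 2 to 13.5 over circular shifts. By the limit set beforehand this counts against it, but the value is so near that limit that it was left open after seeing it.

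Promoter peaks in general did not look like the ribosomal ones. A lack of forkhead sequence at promoter summits as a whole is argued against by a ratio to flanks of 1.59 (95% interval 1.39 to 1.81). The word lay at 25.4% of promoter summits against 16.0% of flanks. The ratio is an average, so it cannot exclude that many single promoter peaks arose without the word. A ratio of this size was not particular to RTAAAYA, since the GAGA factor site also stood at 1.59 (95% interval 1.08 to 2.32) at promoter summits. The stricter word GTAAACA stood at 3.09 (2.22 to 4.31) there. If weak peaks near the threshold were the cause, few of the strongest 730 peaks would lie at promoters. Of these, 47.4% did, against an upper limit of 16.2% for random placement. That limit decides little, since pooled relaxed peaks ranked 26272 to 29190 also passed it, at 18.2%. The share was 42.1% in the weakest of the 4 groups by signal, so promoter peaks were not confined to weak ones. Peaks of single libraries are argued against by the share found in all 3 replicates, which was 0.961 times (0.902 to 1.02) that of other peaks. Forkhead words still exceeded flanks by less at promoters than elsewhere, by 9.43 against 16.2 percentage points (permutation p = 0.00075).

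The surroundings of FoxL1 held many weak peaks, which extra copies of the locus in the tagged line could give. Peaks were called against an input, and a matched input should cancel such copies. With 95.5% of genes below FoxL1 the pooled list passed the limit of 95% set beforehand, but the replicates, at 91.7% to 97.9%, lie on both sides of it, so this was left open after seeing them. The bin of 10 kb from 4010079 to 4020078 on 3L, the highest of those counted around the gene, held 15 pooled relaxed summits. The 99th percentile over the genome was 10, but a highest bin is picked from several. Without the peaks within 1000 bp of an IDR summit, 93.3% of genes had fewer than the 21 left, so binding at the locus and extra copies cannot be told apart: the first would need a value under 75% and its exclusion one of 95%.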

How the results depend on the processing

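The alternatives without ribosomal protein genes and with matching among genes near a pooled relaxed summit were chosen after seeing the data. Alternatives without 1 replicate used the leading peaks of the other 2, and no IDR list was made anew. A move from an IDR value to such a value is therefore also a change of list. Of 143 alternative values, 107 kept their direction and side of the threshold or, where there is no single test, stayed near the main value. The overlap of replicates, the promoter share, the forkhead share and its trend with peak strength did so under every alternative run for them. For the overlap, leaving out 1 replicate only left a pair that the main test already covered, with its p-value carried over. Those alternatives, counted among the 107, could not have come out otherwise. Forkhead ratios ranged from 1.50 (windows of 100 bp) to 3.82 (GTAAACA), and reached 1.84 without ribosomal protein genes. No pairing of samples between conditions was possible because there is 1 group. Summits and their own flanks are paired by peak, which Fisher's tests of the motifs did not use. The depth is unknown, which limits what can be said of weak peaks.

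The share of IDR peaks found per replicate moved to 68.4% with 50% reciprocal overlap, 77.0% with summits within 100 bp, 95.1% with 2 times as many leading peaks and 97.4% in the stronger part of the list. The X ratio of 0.852 became 1.07 against pooled relaxed peaks and 0.956 (exact binomial test, adjusted p = 0.54) in the stronger part. Chromosome 4 turned to 2.28 and 3L to 0.993 against pooled relaxed peaks. The 3R ratio was 0.976 in the IDR list. Averaged over the leading peaks of 2 replicates, with 1 left out each time, it was between 1.00 and 1.01. In the stronger part, 4 and not 9 motifs passed, with fewer peaks tested. Words more frequent at summits numbered 168 and less frequent ones 153 in the main test, 107 and 44 in the stronger part, and 260 and 276 with flanks 1000 bp away, where the less frequent ones outnumber the others. Of the gene lists, 4 passed in the main test, 2 with summits within 1000 bp of a TSS, 7 without length matching and 1 (ribosomal proteins) with matching among genes near a pooled relaxed summit. Where construction does not show it, the cause was not tested.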

Other observations

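The 13 gene families below and the single forkhead words were chosen after the main results were seen. Of the 13 families, 2 passed, both with fewer peaks than length-matched lists. Cytochrome P450 genes, which encode oxidases of hormones and foreign compounds, carried peaks in 3 of 85 cases against 10.96 (permutation test, adjusted p = 0.043), at Cyp310a1, Cyp6d5 and Cyp6u1. Cuticle protein genes did so in 1 of 70 cases against 7.62 (permutation adjusted p = 0.043), at Cpr65Av. Nuclear hormone receptor genes, with 11 of 17 against 5.92, missed the threshold (permutation adjusted p = 0.069), among them EcR, Eip75B, Eip78C and ERR. Mitochondrial ribosomal protein genes had 11 of 73, or 1.83 times the matched mean (permutation adjusted p = 0.14), and translation initiation factors 11 of 44 against 7.13 (adjusted p = 0.22). Proteasome subunits had 3 of 48 against 4.86 (permutation adjusted p = 0.64), and tetraspanins 10 of 34 against 5.25 (adjusted p = 0.14). Histone, odorant-binding protein, E(spl) complex, Rab, septate junction and respiratory complex I genes did not pass either (permutation adjusted p = 0.1, 0.2, 0.16, 0.64, 0.73 and 1).

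Forkhead words differed in how far they exceeded flanks. GTAAACA stood at 3.82 times (95% interval 3.09 to 4.73) and GTAAATA at 2.81 (2.35 to 3.37), while ATAAACA stood at 1.75 (1.48 to 2.08) and ATAAATA at 1.25 (1.09 to 1.43). The related words GCAAACA (2.53), ACAAATA (2.46), ACAAACA (2.28), GTCAACA (2.62) and GTCAATA (2.93) lay between GTAAACA and ATAAACA. Windows with 2 RTAAAYA words made up 5.55% of summits and 1.66% of flanks. Over all 209 other orders of the letters of RTAAAYA, the median ratio to flanks was 1.14, so words of the same letters were also somewhat more frequent at summits. The forkhead ratio was 1.59 times that median. The highest ratio of another order was 1.75, for TAAAYAR, which shares most of the word.

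A hypothesis is that the authors' threshold leaves out forkhead sites. RTAAAYA was 1.37 times as frequent as in flanks (95% interval 1.25 to 1.50) at the 2919 summits ranked next after the IDR list, which is consistent with it. At the next 2919 the ratio was 1.07 (0.968 to 1.17, Fisher's exact test, p = 0.2), although GTAAACA was still 1.70 times as frequent (p = 4.5e-06). At ranks 8758 to 11676 RTAAAYA did not differ from flanks (ratio 0.937, Fisher's exact test, p = 0.24), and from rank 11677 to 29190 it was less frequent at summits. GTAAACA was 1.46, 1.31 and 1.40 times as frequent as in flanks at ranks 8758 to 11676, 11677 to 14595 and 14596 to 17514 (Fisher's exact test, unadjusted p = 0.0049, 0.049 and 0.015). In the 4 later groups of 2919, from rank 17515 to 29190, its ratio ranged from 0.893 to 1.32 and did not differ from 1 (Fisher's exact test, unadjusted p = 0.087 to 1).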
